A study of Populus ussuriensis with 2 samples.

How the data were processed

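RNA was measured by RNA-seq in 2 libraries from Populus ussuriensis, a poplar. Both came from the lowest part of stem cuttings, a piece of 0.5 cm, and the labels give both the same tissue and the same age, day 14 after cutting. The series is described as a time course of adventitious root development, adventitious roots being roots that form on non-root tissue such as a cut stem. The labels hold no second condition, so both libraries were placed in 1 group (n = 2), as replicate 1 and replicate 2 in accession order. Nothing in the labels says whether they came from separate cuttings or cultures, nor what their short titles stand for. Differences between them therefore measure only the spread between these libraries, which may be technical or may be a stage of the time course that the labels do not state. Other times of the series were not analysed here.

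Each file gives 1 value per transcript ID, an FPKM (fragments per kilobase of transcript and 1000000 mapped fragments), per the file headers. The FPKM were computed by the authors. The submitters' processing notes name Bowtie2 2.2.3 and HISAT2 2.1.0 with no role for either. The program that computed FPKM, the genome build, the annotation release and any filter are not given in the sources used here. Without the build and annotation, the listed IDs cannot be taken as gene models of P. ussuriensis itself. The deposited IDs have the form Potri.009G030800.2, in which the last number was read as the transcript and the rest as its locus. Both files list the same 65535 transcripts of 36385 loci in the same order. With the header each file has 65536 lines, which is also a power of 2, and the list stops among IDs whose number field is 17. Transcripts that would follow were not analysed here, so every sum or share below is over the listed transcripts only.

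No gene names, descriptions or coordinates are paired with the IDs, and no genome was used. The 23 gene lists fixed before the data were examined (auxin, cytokinin, ethylene and jasmonate genes, root initiation factors, cell cycle, cell wall, photosynthesis, xylem, phloem, periderm and others) therefore could not be matched to IDs, and none was used. The rule for named transcripts, also fixed before the data were examined, then allowed the 2 most abundant IDs and the 2 IDs highest in each direction by ratio. The ratio was ranked as log2(FPKM + 1) of replicate 2 minus that of replicate 1, among transcripts called apart and above 0 in both libraries. This understates the change of low transcripts.

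A transcript or locus was called detected at an FPKM of at least 1. The design assumed counts if the files held them. As they hold FPKM, the plan's form for normalized values was used: a transcript was called apart where the 2 libraries differed at least 2-fold and their mean FPKM was at least 1, with no test. Values per locus are sums of the FPKM of its listed transcripts. The leading transcript of a locus is the one with the highest FPKM. Correlations across transcripts used log2(FPKM + 1). They are across transcripts, which are not independent replicates. FPKM were used as deposited. Scaling each library to the same listed sum, or by the median of ratios, was tried as an alternative, as were other detection minimums, folds and pseudocounts and leaving out each replicate.

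The files give no depth, but the values keep a trace of it. For most loci with 1 listed transcript, the ratio of the 2 FPKM values is a ratio of whole numbers times 1 constant. The constant, which is the FPKM of 1 read in replicate 2 over that in replicate 1, was read from the commonest ratio among values under 1 FPKM and was 0.876. With it, 84.2% of the 12813 single-transcript loci above 0 in both libraries gave a ratio of whole reads within a relative tolerance of 1e-08 and a product of reads up to 1000000. With a constant wrong by a factor of 1.0123, 0.515% did. Of the 897 such loci under 0.3 FPKM in both libraries, 20.1% did not give whole reads with a product of reads up to 10000. Transcript lengths were taken to be whole numbers as well, and 71.5% of the 4421 loci that set the unit of length gave one within 0.01 of a whole number. Each locus's length was then matched within a relative tolerance of 2e-08. This implied totals of 10957285.72 in replicate 1 and 12513099.14 in replicate 2, so that replicate 2 was 1.14 times as deep. These totals rest on the lengths having no common factor, which would lower them and which the values cannot show. Recovered lengths outside 100 to 16000 were left out, which kept 10032 loci (78.3%). If reads were whole, the recovered reads are lower bounds wherever reads and length share a factor. Reads divided in simple fractions could also pass, with reads and length both recovered too high. How often this happened was not tested. Whether 1 unit is a read or a read pair is not known; reads is used for both.

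The recovery of reads was devised after the data were seen. The reads and lengths served for a count test, for the spread expected from counting, for the test at an assumed variation between libraries and for the checks of counting error, length and neighbouring loci in the closing section. In the count test, loci with at least 10 reads over both libraries were compared by a two-sided exact binomial test given the totals, with Benjamini-Hochberg adjustment at 0.05 and a 2-fold minimum. Such a test compares these libraries, not conditions, and covers counting error only. On simulated data with the totals, lengths and levels of these 10032 loci and 200 changed loci, recovery was exact for 85.1% of the recovered loci and too high for 0. All simulated reads were whole, so the simulation cannot show reads that come out too high because they were divided. The test called 37.5% of the 40 tested loci changed 2-fold, 88.2% of the 76 changed 3-fold and 89.9% of the 79 changed 4-fold, and 3 of 8039 unchanged loci. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.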

Results

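Transcript levels were measured in the basal ends of poplar stem cuttings at day 14 after cutting, in 2 libraries with the same labels. The files name no second condition. The data therefore answer which transcripts were listed as present at the stem base, how the FPKM of each locus was divided among its transcripts, and how far the 2 libraries agreed. The implied depth was 10957285.72 reads in replicate 1 and 12513099.14 in replicate 2, if transcript lengths have no common factor. At this depth a single-transcript locus near 1 FPKM rested on a median of 11.5 reads in replicate 1, over 318 such loci. Intervals on reads would cover counting error only.

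Mostly the same transcripts ranked highest in both libraries, each with a small share of the total. The most abundant, Potri.009G030800.2, reached 8641 ± 1245 FPKM (SD, n = 2), with 9522 FPKM in replicate 1 and 7760 FPKM in replicate 2. It held 1.72% of the listed FPKM in replicate 1 and 1.45% in replicate 2. The next, Potri.010G013400.1, reached 5155 ± 281 FPKM (SD, n = 2). Each made up nearly the whole of its locus, 98.5% for Potri.009G030800.2 in both libraries, and 99.97% and 99.95% for Potri.010G013400.1. The files give no name or function for either. The 10 most abundant transcripts together held 6.43 ± 0.44% of the listed FPKM and the top 100 held 16.98 ± 0.96% (SD, n = 2). Of the top 10, 9 were shared by both libraries, and of the top 100, 92 were shared.

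Of the 36385 listed loci, 20562 (56.5%) reached 1 FPKM in both libraries. Replicate 1 had 21203 such loci and replicate 2 had 21134. Another 9079 loci (25.0%) were listed at 0 in both libraries. Among single transcripts, 28495 were detected in replicate 1, 28287 in replicate 2 and 26041 in both. Of the level classes, loci of moderate level held the largest part of the listed FPKM. Loci from 10 to under 100 FPKM, 9922 in replicate 1 and 9931 in replicate 2, held 48.9% and 50.5% of the listed FPKM. The loci at 1000 FPKM or more numbered 25 in replicate 1, with 10.6% of the listed FPKM, and 22 in replicate 2, with 9.08%.

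Loci with several listed transcripts were detected far more often than loci with 1. A locus with several sums more values against the same detection minimum, and the basis on which transcripts were listed is not given. Of the 13032 loci with several listed transcripts, 88.0% were detected in both libraries and 2.71% were listed at 0 in both. Of the 23353 loci with 1 listed transcript, 39.0% were detected and 37.4% were listed at 0. Among detected loci the median level was 12.8 FPKM with several transcripts and 8.14 FPKM with 1. The number field of the IDs, which runs from 1 to 17 in these files, separated loci less. The share of loci detected in both libraries was lowest for field 11, at 46.3% of 1700 loci, and highest for field 6, at 61.0% of 2814 loci. Field 9 held 4.69% of the listed loci and 8.16% of the listed FPKM in replicate 1 and 7.58% in replicate 2, and the most abundant transcript belongs to it. No test was made of these shares, since all come from the same 2 libraries.

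In the deposited values, most loci with several transcripts had the larger part of their FPKM in 1 of them. How the program that computed FPKM divided reads among the transcripts of a locus is not known. These shares may therefore reflect that division as well as expression. Among the 11463 such loci detected in both libraries, the leading transcript held a median of 91.9% of the locus FPKM in replicate 1 and 91.8% in replicate 2. A single transcript held over 50% in 94.95% of loci in replicate 1 and 95.04% in replicate 2. For the 4918 loci with 2 listed transcripts this says little, since a leader of 2 holds at least 50% by definition. At least 2 transcripts were detected in 46.4% of loci in replicate 1 and 46.1% in replicate 2. The leading transcript was the same in both libraries for 10445 loci (91.1%), against 36.3% if a leader were drawn at random among the listed transcripts. For the 1308 of these loci with a mean of at least 50 FPKM, the leader was the same in 1256 (96.0%). Transcript number 1 was the leader in 56.3% of loci in replicate 1 and 57.6% in replicate 2. Its lead fell with the number of listed transcripts, from 70.1% of loci with 2 to 28.8% of loci with 6 or more in replicate 1. A leader drawn at random would fall from 50% to 14.1%. The leading transcript's share fell likewise, from a median of 100% to 69.1% in replicate 1.

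**Figure D1:**
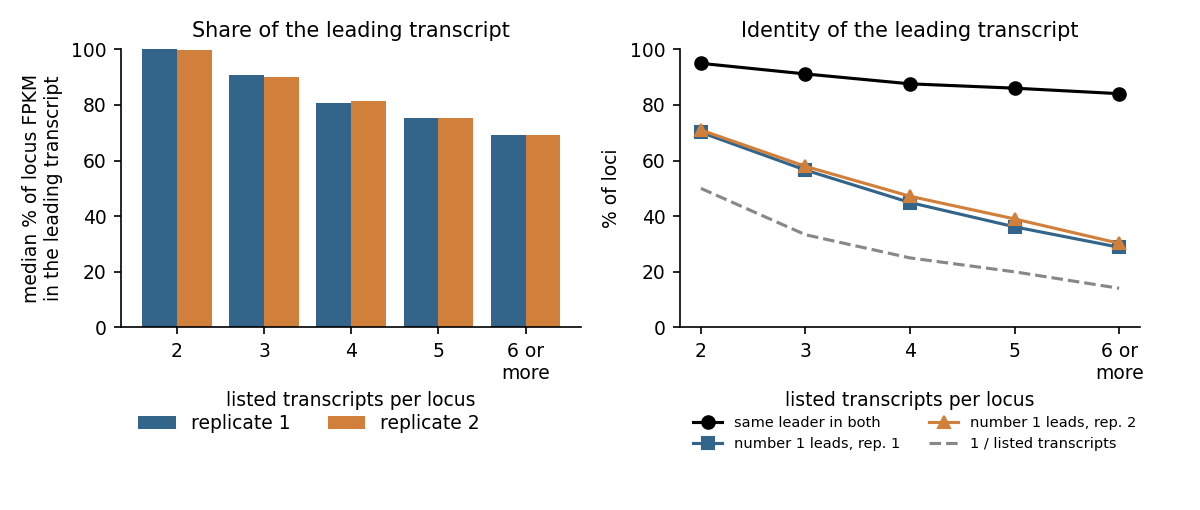
Left, the median share of a locus's FPKM (percent) held by its leading transcript, against the number of listed transcripts per locus, for replicate 1 and replicate 2 as bars. Right, the percentage of loci whose leader was the same in both libraries (black), the percentage led by transcript number 1 in each library (colours) and the value for a leader drawn at random (dashed). The same leader was found in 94.9% of loci with 2 transcripts and 84.0% of loci with 6 or more.

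The libraries were close for abundant loci and drifted apart at low levels. Across 44570 transcripts above 0 in either library, Pearson's r of log2(FPKM + 1) was 0.95 and Spearman's rho was 0.90. Across 27306 loci, r was 0.98 and rho was 0.98. For loci of 100 FPKM or more, the log2 ratio of replicate 2 to replicate 1 had a median of -0.07 and an SD of 0.29 (814 loci). For loci from 1 to under 5 FPKM the SD was 0.72 (5898 loci above 0 in both). The median log2 ratio of detected loci lay between -0.05 and -0.01 in each of the 17 number fields, so no field stood apart. No transcript above 0 had equal values in both files.

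A minority of transcripts differed 2-fold, and mostly at low levels. Of 28654 transcripts with a mean of at least 1 FPKM, 3880 (13.5%) differed at least 2-fold, 2007 higher in replicate 2 and 1873 higher in replicate 1. Of these, 290 were listed at 0 in replicate 1 and 308 in replicate 2. Their median level was 2.26 FPKM, against 7.71 FPKM for the other transcripts. Summed per locus, the number was 1069 of 21247 loci (5.03%), 637 higher in replicate 2 and 432 higher in replicate 1. Among the 2037 loci with a mean of at least 50 FPKM, 27 were higher in replicate 2 and 10 in replicate 1. No test is attached to these counts, because each value has 1 library on each side.

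Among transcripts above 0 in both libraries, the 2 farthest apart in each direction belonged to loci whose sums were less than 2-fold apart. These sums were 1.05-, 1.22-, 1.36- and 1.05-fold apart in the order given here. Potri.014G004700.1 was at 0.0011 FPKM in replicate 1 and 20.3 FPKM in replicate 2. The other transcript of its locus was at 21.3 FPKM in replicate 1 and listed at 0 in replicate 2, and the locus sum was 20.8 ± 0.72 FPKM (SD, n = 2). Potri.008G002900.13 went from 0.044 FPKM in replicate 1 to 23.8 FPKM in replicate 2, while the other 12 transcripts of its locus summed to 105.4 and 104.7 FPKM. In the opposite direction, Potri.007G008500.3 was at 77.5 FPKM in replicate 1 and 0.333 FPKM in replicate 2, in a locus that summed to 1259 and 925 FPKM. The other 4 transcripts of that locus also fell, from 1182 to 925 FPKM. Potri.006G203000.6 was at 29.9 FPKM in replicate 1 and 0.014 FPKM in replicate 2, while its locus summed to 103.0 and 108.7 FPKM. On the log2(FPKM + 1) scale these 4 differences, replicate 2 minus replicate 1, were 4.41, 4.57, -5.88 and -4.93. Among the 19035 transcripts of loci with several that had a mean of at least 1 FPKM, 3130 (16.4%) differed 2-fold. In 348 of the 3130 (11.1%) the locus sum also differed 2-fold in the same direction. A transcript with a small share of its locus cannot move the sum 2-fold by itself, so the rest need not have exchanged reads. Loci led over 50% by different transcripts in the 2 libraries numbered 642 of 11463 (5.60%).

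**Figure D2:**
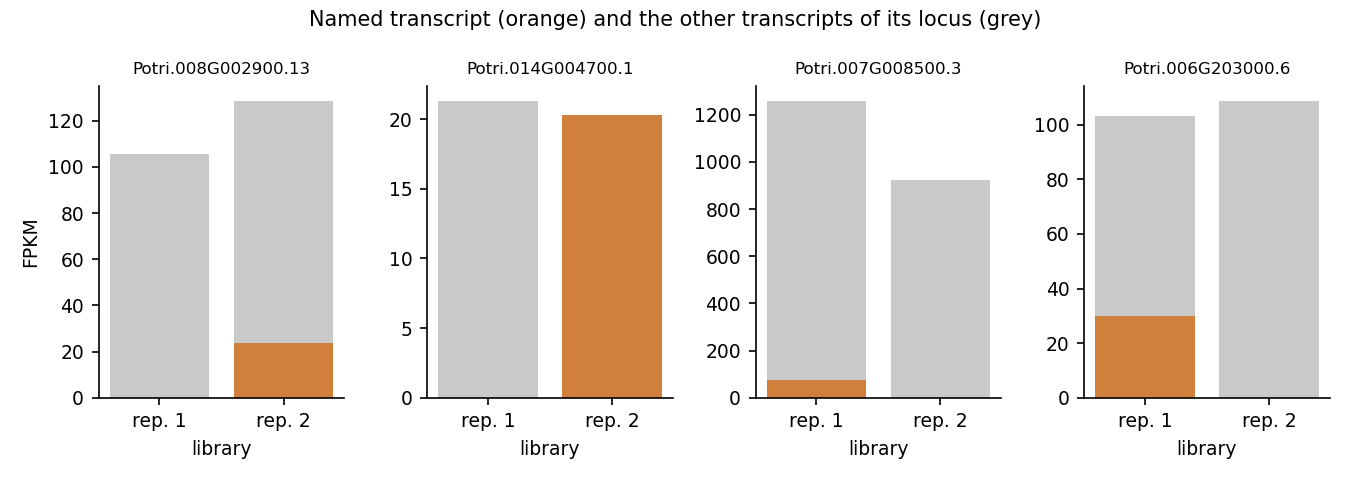
FPKM in replicate 1 and replicate 2 of 4 transcripts (orange) and of the other listed transcripts of the same locus (grey, stacked), each panel with its own scale. The 4 are the 2 farthest apart in each direction among transcripts above 0 in both libraries. For Potri.014G004700.1 the locus kept 21.3 and 20.3 FPKM while its 2 transcripts exchanged places.

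Single-transcript loci, which cannot exchange reads among listed transcripts, also differed between the libraries. Of 9619 with a mean of at least 1 FPKM, 750 (7.80%) were 2-fold apart. On the recovered reads, 1793 of 8619 loci (20.8%) were past the exact binomial test at a Benjamini-Hochberg adjusted threshold of 0.05, and 515 of these were at least 2-fold apart, 315 higher in replicate 2 and 200 higher in replicate 1. This test covers counting error alone and takes the recovered reads as whole, so loci with divided reads may pass it wrongly. With a variation between libraries of 20% assumed on top, 160 loci were called, 132 of them higher in replicate 2, and with 40% assumed, 2 were called, both higher in replicate 2. The chi-square of the reads against 1 shared profile was 8.63 times its degrees of freedom, which is far beyond the noise of sampling 1 library again. Among loci of 1000 reads or more, the limit on the product of reads favoured unequal reads, which may raise this value. In loci with a mean of 300 to under 1000 reads the log2 ratio had an SD of 0.43 and a robust SD of 0.26, against 0.095 from counting (1640 loci). In this class the excess over counting corresponds to a coefficient of variation of 11.8% from the robust SD and 20.6% from the SD. Over all 5 read classes it ranged from 11.8% to 18.4% and from 20.6% to 31.8%. The log2 ratio also moved with recovered transcript length: its median was -0.10 in the 1665 shortest loci with at least 20 reads in both libraries and 0.04 in the 1665 longest.

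**Figure D3:**
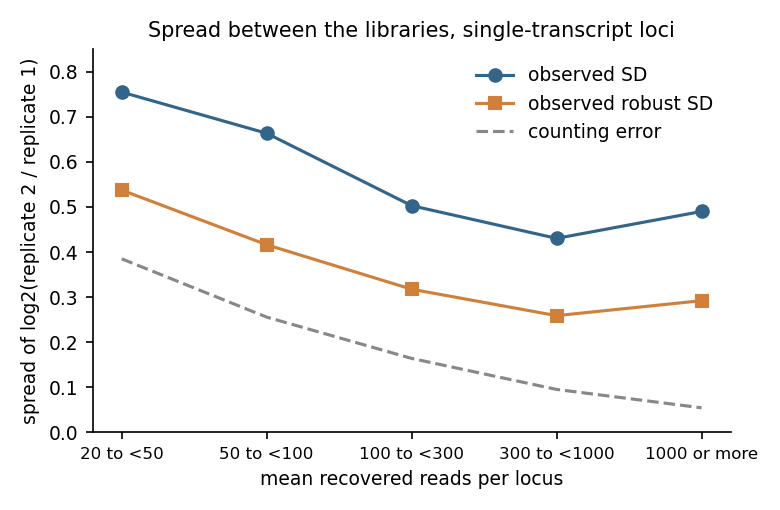
Spread of log2(replicate 2 / replicate 1) among single-transcript loci, by mean recovered reads per locus: the SD, the robust SD (from the median absolute deviation) and the SD that counting alone would give. Both observed lines lie above the dashed counting line in every class, from 0.54 against 0.39 (robust SD) at 20 to under 50 reads to 0.29 against 0.054 at 1000 reads or more. In that last class the limit on the product of reads favoured unequal reads, which may raise the observed spread.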

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

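The number of transcripts detected in both libraries (26041 at 1 FPKM) was 35219 at a minimum of 0.1 FPKM and 15227 at 5 FPKM. Either library alone gave 28287 to 28495, and the shares of the top 10 and top 100 transcripts ranged from 6.12% to 6.74% and from 16.3% to 17.7%. Pearson's r (0.952) was 0.883 with a pseudocount of 0.1, 0.970 with 5, 0.954 for transcripts at 1 FPKM or more in both and 0.980 for locus sums. The 3880 transcripts 2-fold apart became 3872 under median-of-ratios scaling and 3863 under the same listed sum, with 55.0% and 55.5% higher in replicate 2 against 51.7% as deposited. They numbered 7692 at 1.5-fold, 1328 at 4-fold, 14811 with no minimum level and 882 at a mean of at least 5 FPKM, with 48.7%, 55.6%, 49.9% and 60.8% higher in replicate 2, so that the majority turned at 1.5-fold (3747 against 3945) and with no minimum (7396 against 7415). Alternatives chosen after seeing the data gave 2267 for the ratio of FPKM + 1, 1069 for locus sums, 750 for single-transcript loci and 515 for the exact binomial test on recovered reads. On the same reads the test gave 160 with an assumed variation of 20% and 2 with 40%. The fall from 515 to 160 and 2, on the same reads, comes from the assumed variation itself; the cause of the other shifts was not tested. All 24 recomputed levels of the 6 named transcripts stayed within 1 SD, which a group of 2 always gives when a replicate is left out. Settings that need gene names (the gene lists, and leaving out organelle and ribosomal RNA genes) and the dispersion estimate over all genes were not run. No paired analysis was possible because the labels give 1 group. Low depth limits the low end: at 1 FPKM a locus holds about 11.5 reads.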

Other observations

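Neighbouring loci of the ID order resembled each other weakly in level. Over 12485 pairs of adjacent detected loci, the rank correlation of mean level was 0.047, above the highest of 100000 permutations (0.039; permutation p = 1e-05, the smallest they can give, adjusted 1.7e-05 over 5 such tests). It was 0.034 at 2 places, 0.030 at 5 places and 0.008 at 10 places along the list. This is consistent with levels being shared along the list, though coordinates were not used here and the order of the IDs stands in for position. Loci are not independent replicates. The tests in this part were written down before their results were seen, except those named next. The count of single-transcript loci past the binomial test and the counts of adjacent loci 2-fold apart were chosen after. So was the use of whole-read pairs as a check on divided reads.

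The first pattern is the 3880 transcripts 2-fold apart. In the 2553 loci with several transcripts that hold such a one, the change of the leading transcript was set against that of the others. The rank correlation was -0.46 (95% bootstrap interval -0.49 to -0.42), and the 2 changes were in opposite directions in 65.5% of these loci. Reads divided differently within a locus may therefore account for some of that part. Whether the quantification or splicing moved them was not tested. Such a division cannot account for single-transcript loci, of which 515 were past the exact binomial test and 2-fold apart at any level. Of those, 436 had a mean of at least 1 FPKM as in this pattern. Single-transcript loci were, however, apart at 0.474 times the share (0.439 to 0.512) of transcripts in other loci. This value leaves the weight of such a division over all transcripts open. Counting error accounts for only part of the pattern. Of the 7562 loci with recovered reads and a mean of at least 1 FPKM, 576 were 2-fold apart. Simulations with counting alone, which took the recovered reads as whole, gave 100 to 139 (at most 153). From 5 to under 50 FPKM counting gave a median of 3 where 186 were seen. Rescaling left 0.998 times as many transcripts and removing a length trend left 278 of 6658 loci, as many as before, and a difference in stage or cutting between the libraries stays open and untested, since the labels describe them alike.

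The second pattern is a shift with transcript length. Among 6658 single-transcript loci with at least 20 reads in both libraries, the log2 ratio of replicate 2 to replicate 1 rose with recovered length with a rank correlation of 0.155 (bootstrap interval 0.131 to 0.179). The median log2 ratio went from -0.10 in the 1665 shortest loci (median length 766) to 0.04 in the 1665 longest (median length 2662). A shift with mean FPKM does not account for it, as the correlation was 0.157 after mean FPKM was matched. At equal FPKM a longer locus holds more reads, so this matching cannot exclude a shift with read number. The median log2 ratio rose with reads too, from -0.081 at a mean of 20 to under 50 reads to -0.010 at 300 to under 1000. Whether the minimum of 20 reads in both libraries favoured low ratios among loci of few reads was not tested. A length bias of the libraries, for example from fragment size or RNA integrity, may be the source, but 0.155 lies between the bounds set in advance (0.1 and 0.2), and genes of different length that truly differ cannot be told apart from it with 1 library on each side.

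The third pattern is that adjacent loci differed between the libraries in the same direction. Their log2 ratios had a rank correlation of 0.043 over 12485 pairs (permutation p = 1e-05, the smallest possible, adjusted 1.7e-05), which was 0.018 at 2 places and 0.005 at 5 places. Adjacent loci both 2-fold higher in replicate 2 numbered 29, against a median of 12 and at most 25 when calls were permuted. Pairs both higher in replicate 1 numbered 9, against a median of 5 and at most 15. Pairs in opposite directions numbered 14, against a median of 16 and at most 28. The correlation did not fall in the 1679 pairs with whole reads, at 0.092 (0.045 to 0.139, permutation p = 0.00019, adjusted 0.00024). Reads divided fractionally between near-identical copies stay open, because reads divided in simple fractions can pass as whole. These pairs are also only a part of the 12485. A shift with mean FPKM does not account for the pattern, since matching mean FPKM left 0.044. Nor does one with length among the whole-read pairs, since matching lengths left 0.085 of that 0.092 (0.039 to 0.133, permutation p = 0.00049, adjusted 0.00049). Shared reads that were given whole to 1 copy stay open as well, because the program that made the values is not given. Co-regulated neighbours or reads running from a locus into the next may also explain the pattern and were not tested.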
